A study of Oncorhynchus mykiss with 17 samples.

How the data were processed

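Whole rainbow trout sac-fry of the NCCCWA breeding programme were profiled by reduced representation bisulfite sequencing, which enriches CpG-rich fragments and reads unmethylated cytosines as thymines. Libraries were made with the Ovation RRBS Methyl-Seq kit, per the labels' protocols. Diet, family and sire were taken from the sample titles, which give 5 Low, 6 Medium and 6 High libraries. A Low library of family B sire 2 was not analysed here. The file of Low family A sire 1 carries in its name a code that elsewhere goes with family B sire 2, and the label of the title was kept. Expression libraries and later time points were not analysed here.

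Each library had a table of CpG positions made by the authors, with a count of reads covering the position (coverage) and the percent of those reads called methylated or unmethylated, per the file headers. Bismark 0.19.0 and methylKit are named in the submitters' processing notes without their roles. Tested on the files, every position had at least 10 reads, the 2 strands of a CpG were separate positions, and coverage times percent gave whole methylated reads to within 0.198. The genome build was not given in the sources used here. Positions are those of the authors' files. Gene names and neighbours came from a RefSeq gene table of the assembly USDA_OmykA_1.1, matched by chromosome name, and none of its coordinates is printed. As a check of this match, 89.94% of CpGs within 1 kb of a gene end were below 20%, against 28.94% to 47.24% in 20 shuffles of the chromosome names.

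The authors also deposited 2 tables of differential CpGs within 10 kb of a transcript (distance, promoter, exon and intron flags, island or shore, and hyper- or hypomethylated), and 2 tables joining these to expression. Per the file headers the joined tables hold the mean normalised expression signal, a log2 fold change with its standard error, a test statistic (a score), and a p-value with its adjusted p-value, as deposited by the authors. The test, the thresholds and the reference diet of the deposited tables are not given in the sources used here. Each joined table also has 18 columns of per-library values under names that match no sample, and these were not used.

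Methylated reads were rebuilt as coverage times percent, rounded. For each pair of diets a quasi-binomial logistic model was fitted per CpG to the libraries of those 2 diets, with family as an additive block. The dispersion was moderated across all tested CpGs by the method of limma's squeezeVar, rewritten in Python, and never taken below 1. A call needed an F test with a Benjamini-Hochberg adjusted p under 0.05 and a family-averaged difference of 10 points or more. A CpG was tested with at least 10 reads in at least 4 libraries of each diet, not counting libraries of a family that was read in 1 of the 2 diets alone. The same model was used on reads summed over 1 kb tiles with at least 3 CpGs and over protein-coding genes with 10 kb on either side and at least 5 CpGs. A trend over choline ppm, a diet by family interaction (at least 15 libraries) and family differences were tested in all 17 libraries. The mean level was compared by two-sided exact permutation of diets within families. A sum over a gene or tile takes whichever positions each library holds, so it can differ between libraries that have equal levels at every shared position.

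The design, the alternatives and 11 gene lists were fixed before the data were examined. List membership went by gene symbol with set endings, which also took cth1, tbx22 and syt12. The text names the 10 highest and 10 lowest differences among called CpGs, or, where under 5 CpGs pass, the 5 of smallest p. It also names list genes with a call, genes with at least 3 called CpGs in a deposited table and genes in both deposited tables. Some genes of the deposited tables are not reported here. Naming tiles and genes from those of small p, with tiles near genes preferred, and list members that did not pass, was chosen after the values were seen. Parts of the plan could not be run: ranking deposited CpGs by difference, since the tables give directions only; promoter, exon and intron classes from the reference, and list phrases on its genes, since the gene table has neither; and a coverage minimum of 5.

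During the analysis 5 sets of CpGs for estimating the dispersion prior were tried with the calls in view: all CpGs, and those with a pooled level of 2 to 98%, 5 to 95%, 10 to 90% and 20 to 80%. The set of all CpGs is the one fixed in advance and gives the values reported, and the others are alternatives. Tested on simulated data with the real depths and 200 seeded CpGs, the moderated test with all CpGs called 0 unchanged CpGs but was cautious. Among unchanged CpGs, 1.69% (High against Medium), 1.43% (Medium against Low) and 1.56% (High against Low) had p under 0.05. With an extra correlation of 0.02 between reads of a library, 50-point differences were recovered at 40.5%, 38.5% and 42.5% and 30-point differences at 2.0%, 0.0% and 0.5%. With the prior from 5 to 95%, 30-point differences were recovered at 80.0%, 80.5% and 81.5% without the extra correlation, and at 51.5%, 47.0% and 39.0% with it. The plain logistic test called 170, 157 and 163 of the unchanged CpGs under that correlation.

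Other alternatives were no family block, a block of family and sire, 20 reads, 3 or 5 libraries per diet, removal of CpGs above the 99.9th percentile of coverage, summed strands, no moderation, a plain logistic test, limma on arcsine square root levels, stricter thresholds (0.01 and 25 points), 500 bp and 5 kb tiles, gene bodies alone, and leaving out each library. Family and sire numbers are shared between diets. Over 15 pairs of libraries of the same family and sire, deviations from the diet means correlated at 0.04 on average (-0.093 to 0.139). The average was 0.007 over the 29 pairs of the same family, which include these, and -0.003 over 56 pairs of different families. The pairs are not independent, so this does not settle whether a shared number marks the same sire. Where nothing says that libraries came from separate fish, p-values measure the spread between these samples.

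Deposited CpGs were placed by matching the pattern of their distances (2 of 14 transcripts placed) or, for transcripts with a symbol, within the gene's window (7 of 27). As controls chosen afterwards, the match was repeated with the wrong orientation and with windows shifted in steps of 20 kb. The wrong orientation placed 1 and 4 transcripts, and the first version of this control was misleading because symmetric spacings hit the same positions. Without identical positions 5 CpGs remained, 3 with the deposited direction, and a median absolute difference of 7.7 points against 63.9 for the stated orientation. Over 18 shifts at most 2 transcripts were placed, 0.72 on average. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.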

Results

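CpG methylation was measured by reduced representation bisulfite sequencing in whole rainbow trout (Oncorhynchus mykiss) sac-fry at 0 days after hatching. Their mothers had been fed a diet with 2065 ppm (Low), 5657 ppm (Medium) or 9248 ppm (High) choline, a methyl donor precursor and a part of phosphatidylcholine. The 17 libraries came from families A, B and E and from 2 sires per family, with 5 Low, 6 Medium and 6 High libraries. Each library was a separate sample by its title. Whether a library held 1 fish or several was not given in the sources used here. The files held from 11722 CpG positions (Medium family B sire 2) to 356918 (High family A sire 2), each with 10 reads or more. The next smallest library had 111125 positions. The median coverage per position was 11 to 14 reads, and at 12 reads a level of 50% has a 95% Wilson interval of 25.4% to 74.6%. This interval covers counting error only, since no molecular identifiers were in the files. The question of the series was which methylation levels in the offspring differ with maternal choline, beside changes in expression, which were not analysed here except through the authors' deposited tables.

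The sac-fry genome was highly methylated away from genes and sparsely methylated at gene ends. CpGs within 1 kb of a gene end had a mean level of 9.2%, and 89.9% of them were below 20%. CpGs more than 5 kb from a gene end had a mean level of 78.2%, and CpGs farther than 10 kb from any gene 80%. Levels correlated between libraries with Pearson's r of 0.883 to 0.953 across CpGs, which are not independent replicates.

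No difference in mean methylation between diets passed the test. Over the 16573 CpGs read in the 16 libraries other than Medium family B sire 2, the mean level was 78.4% ± 0.76 (SD, n = 5) in Low, 79.3% ± 0.76 (n = 5) in Medium and 79.3% ± 0.74 (n = 6) in High. The family-averaged differences were 0.164 points for High minus Medium, 0.596 for Medium minus Low and 0.76 for High minus Low. In a two-sided exact permutation test of diets within families, these gave p = 0.7407, 0.25 and 0.1852, or 0.7407, 0.375 and 0.375 after Benjamini-Hochberg adjustment. The lowest libraries were both Low family A libraries. Without both, which leaves families B and E and was chosen after the values were seen, the differences were -0.276 (Medium minus Low) and -0.004 (High minus Low). Without Low family B sire 1, which leaves families A and E, they were 1.407 and 1.429 (exact p = 0.0556 each). With 36 arrangements this is the smallest p that the test could give. Without High family B sire 2, High minus Low was 0.979 (exact p = 0.0278). Near gene ends the levels of the diets were also close, at 18.7% ± 0.63 in Low, 19.1% ± 0.32 in Medium and 18.8% ± 0.37 in High over 827 common CpGs.

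**Figure D1:**
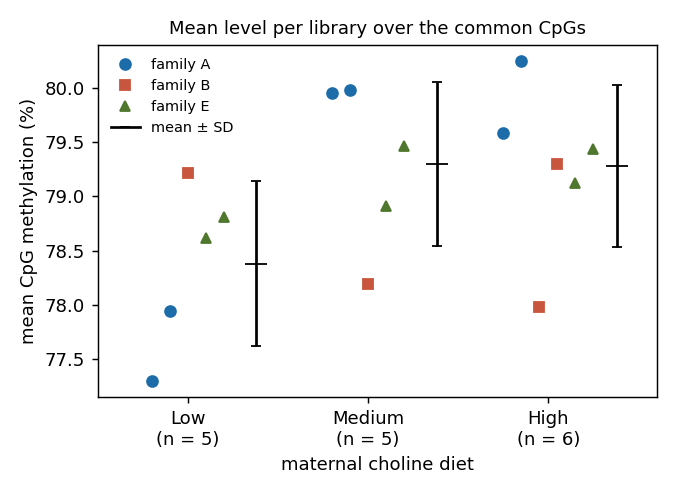
Mean CpG methylation (%) of each library over the 16573 common CpGs, by maternal diet, with points marking families and bars the mean ± SD (n = 5, 5 and 6). The diets overlap, with means of 78.4%, 79.3% and 79.3%.

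High against Medium asked what choline above the middle level changes. The 1 kb tile of smallest p lay on chromosome 13 near LOC110516540, from 57302001 to 57303000. Methylation there was 29.9% ± 10.01 (n = 6) in High, 67.4% ± 6.97 (n = 4) in Medium and 58.1% ± 7.82 (n = 4) in Low, and all 3 of its CpGs were lower in High. A tile at LOC110536041 and LOC110536042 on chromosome 11 was at 4.4% ± 2.15 in High and 15.3% ± 13.8 in Medium, lower at 8 of 8 shared CpGs. The tile of slc4a1b, a member of the band 3 anion exchanger family of red blood cells, was at 96.3% ± 1.08 in High and 93.4% ± 0.96 in Medium. None of these differences passed the test (adjusted p of 0.56 to 0.96, moderated quasi-binomial test). Here and below, the CpGs of a tile are neighbours read in the same libraries, so their counts restate the tile's difference.

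The 5 CpGs of smallest p between High and Medium did not pass either, with unadjusted p of 0.002 to 0.0025 and adjusted p of 1 in the moderated quasi-binomial test. Position 57302471 on chromosome 13, in the tile near LOC110516540, was at 30.8% ± 10.9 (n = 6) in High and 67.8% ± 3.98 (n = 4) in Medium. Position 23635671 in LOC110485993, also on chromosome 13, was at 97.9% ± 4.17 in High and 57.0% ± 26.5 in Medium (n = 4 each). Position 13616864 in LOC110506268 on chromosome 26 was at 0% in all 5 High libraries and at 11.7% ± 12.4 (n = 5) in Medium. Position 188318 of an unplaced scaffold was at 95.3% ± 1.82 and 89.1% ± 1.04 (n = 6 each). Position 19504362 near LOC110507703 on chromosome 27 was at 63.6% in 1 High library and at 0% in the other 3 High and all 5 Medium libraries.

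No CpG of 43360, no 1 kb tile of 8131 and no gene of 8123 passed the moderated quasi-binomial test with a difference of 10 points or more. At unadjusted p under 0.05 there were 923 CpGs, 394 tiles and 442 genes. Here and below such counts alone are no evidence of a diet effect, since unchanged features also fall under 0.05. In simulated unchanged data 1.69% of CpGs did so in the moderated test, and 3.52% with a correlation of 0.02 between reads of a library. On the same CpGs limma called 2 and a plain logistic test, which takes reads as the only source of spread, called 45 (11 higher and 34 lower in High), and these lists shared 0 CpGs. The moderated test was cautious: in simulated data without extra correlation between reads of a library it recovered 59% of seeded 50-point differences and 19% of 30-point ones for this comparison, and with a correlation of 0.02 it recovered 40.5% and 2.0%.

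Medium against Low asked what the step from the lowest to the middle level changes. At ttbk1a on chromosome 17, a gene for a tau tubulin kinase, the tile from 34378001 to 34379000 was at 68.0% ± 7.71 (n = 4) in Medium and 89.2% ± 3.52 (n = 5) in Low, with all 3 CpGs lower in Medium. The same tile was at 74.8% ± 7.7 (n = 6) in High. A tile on chromosome 20 at LOC118942453, LOC118942452 and LOC118942458 was at 83.0% ± 1.79 (n = 6) in Medium and 72.7% ± 8.22 (n = 5) in Low. It was higher in Medium at 20 of 20 shared CpGs, which are not independent. At tanc2b, which encodes a postsynaptic scaffold protein, a tile was at 96.3% ± 1.77 (n = 5) in Medium and 85.4% ± 6.91 (n = 4) in Low. None of these passed the moderated quasi-binomial test, with an adjusted p of 0.77 each. They were picked because they lie near genes, and tiles with no gene within 10 kb had smaller p. The smallest adjusted p of a tile was 0.38 in the same test. A tile with this value, from 47291001 on chromosome 1, was at 81.4% ± 3.1 (n = 6) in Medium and 64.2% ± 8.57 (n = 5) in Low.

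The 5 CpGs of smallest p between Medium and Low had unadjusted p of 0.00052 to 0.0018 and an adjusted p of 0.99 in the moderated quasi-binomial test. Position 86575781 in LOC118936869 and LOC118936868 on chromosome 10 was at 6.45% ± 4.85 in Medium and 35.6% ± 15.3 in Low (n = 5 each). Position 378203 near LOC118942452 on chromosome 20 was at 76.9% ± 6.75 and 48.1% ± 21.7 (n = 5 each). Position 47291278 on chromosome 1 was at 84.8% ± 3.87 (n = 6) and 65.6% ± 8.92 (n = 5), with no gene within 10 kb. Position 5988359 on chromosome Y was at 70.9% ± 16.6 and 55.5% ± 15.9, and position 70382 of an unplaced scaffold at 68.5% ± 14.0 and 51.4% ± 18.3. The last 2 also had the smallest p between families.

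No CpG of 40882, no tile of 7828 and no gene of 8343 passed the moderated quasi-binomial test between Medium and Low. At unadjusted p under 0.05 there were 1095 CpGs, 479 tiles and 461 genes. The share was 1.43% of CpGs in simulated unchanged data, and 3.36% with the correlation of 0.02. The CpG test by limma called 2 CpGs and the plain logistic test 199, of which 159 were higher and 40 lower in Medium. Without both Low family A libraries, and so without family A, the plain test called 11, with at least 3 libraries per diet. In simulated data the moderated test recovered 45% of 50-point and 11% of 30-point differences without extra correlation, and 38.5% and 0.0% with it. Without the single Low family B library, 1 tile passed.

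High against Low spanned the whole range of choline. The tile near LOC118938645 on chromosome 13, from 57999001 to 58000000, was at 58.96% ± 8.36 (n = 6) in High, 52.8% ± 9.84 (n = 6) in Medium and 46.2% ± 7.16 (n = 5) in Low. Tiles at LOC110522824 on chromosome 5 (88.3% ± 3.08 and 80.3% ± 5.84) and at LOC110536281 on chromosome 11 (92.7% ± 2.1 and 85.2% ± 4.42) were higher in High than in Low at 5 of 5 and 8 of 8 shared CpGs. The family-averaged difference of the ttbk1a tile was -14.91 points. These tiles were picked because they lie near genes. The tile of smallest p, from 1230001 on chromosome 32 with no gene within 10 kb, was at 86.8% ± 4.85 in High and 81.6% ± 7.96 in Low. Each had an adjusted p of 0.78 in the moderated quasi-binomial test, so none passed.

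The 5 CpGs of smallest p between High and Low had unadjusted p of 0.0004 to 0.0019 and an adjusted p of 0.99 in the moderated quasi-binomial test. Position 29957702 near LOC110489970 on chromosome 15 was at 0% in all 5 Low libraries and at 22.9% ± 27.2 (n = 6) in High. Position 73815 on the same chromosome, with no gene within 10 kb, was at 63.2% ± 7.79 (n = 5) in Low, 72.5% ± 15.5 (n = 6) in Medium and 84.1% ± 7.79 (n = 6) in High. The other 3 lay on unplaced scaffolds. Position 470 was at 67.7% ± 8.66 in Low and 85.6% ± 6.27 in High, position 82493 at 76.8% ± 11.2 and 87.7% ± 4.18, and position 82508 at 76.7% ± 13.2 and 86.3% ± 7.43.

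No CpG of 45882, no tile of 8784 and no gene of 9096 passed the moderated quasi-binomial test between High and Low. At unadjusted p under 0.05 there were 1145 CpGs, 522 tiles and 588 genes. The share was 1.56% of CpGs in simulated unchanged data, and 3.66% with the correlation of 0.02. By limma 1 CpG was called, and by the plain logistic test 170, of which 130 were higher and 40 lower in High. Without both Low family A libraries, and so without family A, the plain test called 22, with at least 3 libraries per diet. In simulated data the moderated test recovered 42% of 50-point and 12% of 30-point differences without extra correlation, and 42.5% and 0.5% with it. Without the single Low family B library 2 tiles passed, and without High family B sire 2, 1 tile.

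**Figure D2:**
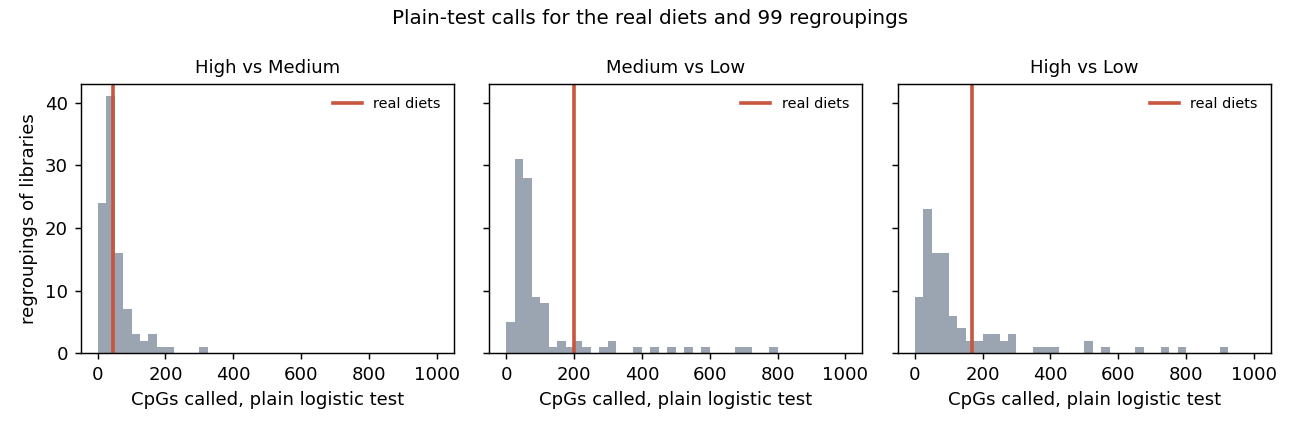
CpGs called by the plain logistic test (horizontal axis) for 99 regroupings of the libraries (vertical axis, grey bars) and for the real diets (red line), per diet comparison. The real counts of 45, 199 and 170 lie inside the range of the regroupings, whose highest counts were 308, 782 and 902.

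Summed over whole genes with 10 kb on either side, reads of the diets were far apart at some genes. At the positions shared between diets, a part of each gene, the levels of the diets mostly lay closer together. For trip11, which encodes a Golgi-associated protein, the sums gave 1.5% ± 1.01 (n = 6) in High, 5.23% ± 3.92 (n = 6) in Medium and 22.8% ± 12.7 (n = 5) in Low. At its 15 positions read in at least 2 libraries of both diets, the mean was 1.24% in High and 1.92% in Low. For gclc, the catalytic subunit of the first enzyme of glutathione synthesis, High minus Medium was 12.6 points by sums and 0.32 at 13 shared positions. For nfxl1, High minus Low was 51.2 points by sums and 1.55 at 8 shared positions. The kinesin gene kif5aa was 44.0 points higher in Medium than in Low by sums and 6.03 points higher at 6 shared positions. Shared positions were 15 of the 41 read at trip11 and 8 of the 56 read at nfxl1. Levels as low as at those of trip11 leave little room for a difference. Positions that were not shared were not compared between diets, so a difference there stays open.

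Of the genes listed by smallest p, zgc:103625 on chromosome 13 kept its difference: High minus Medium was -15.03 points by sums and -14.59 at shared positions, lower at 12 of 12. It had an adjusted p of 0.55 in the moderated quasi-binomial test, and trip11, with the smallest p of any gene, had 0.13. Over all 9089 genes with enough positions, the 2 kinds of High minus Low difference correlated across genes at r = 0.205. Of 1793 genes 10 points or more apart by sums, 47 were that far apart in the same direction at shared positions. This comparison of positions was chosen after the gene sums were seen.

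**Figure D3:**
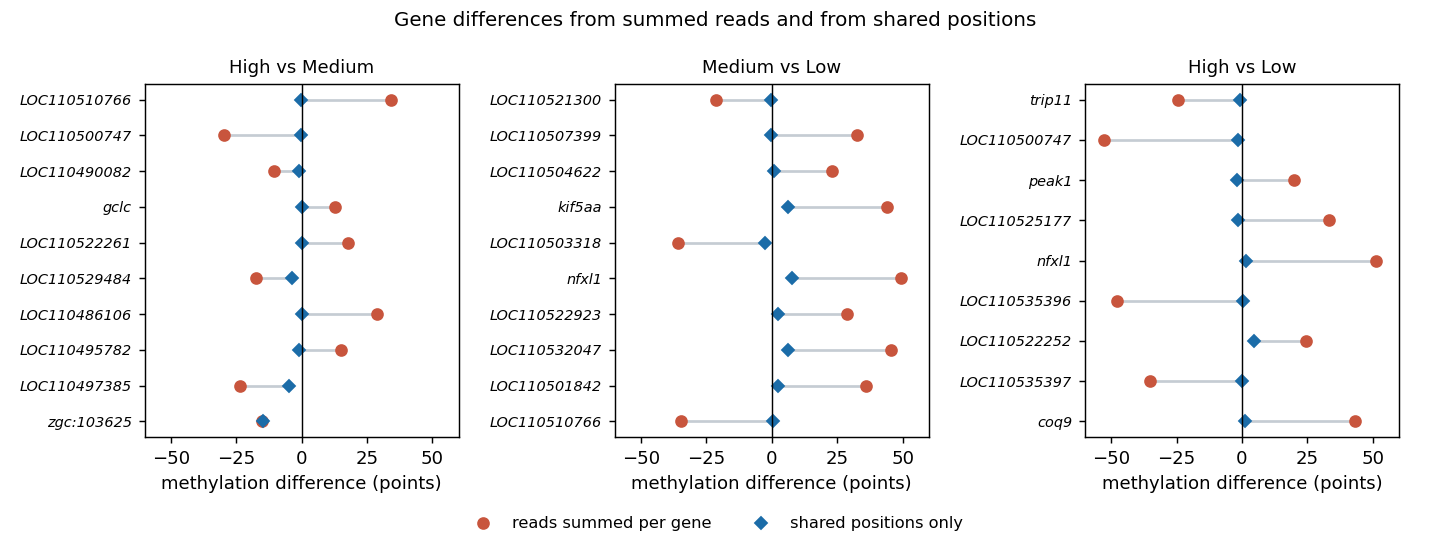
Methylation difference (points, horizontal axis) of the genes with the smallest p in each diet comparison and at least 4 shared positions, from reads summed per gene (circles) and as the mean over positions read in at least 2 libraries of both diets (diamonds). Sums of trip11 differed by -24.49 points and its shared positions by -0.68, while both values of zgc:103625 lay near -15.03.

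No CpG trended with choline ppm past the threshold among 37747 in the moderated quasi-binomial test, 1647 had an unadjusted p under 0.05, limma called 0 and the plain logistic test 279 (245 rising and 34 falling by its fit). The 5 of smallest p included positions 73815 on chromosome 15 and 470 of an unplaced scaffold, already described. Position 26523 of an unplaced scaffold was at 39.8% ± 7.77 (n = 5), 51.0% ± 9.38 (n = 6) and 56.8% ± 7.0 (n = 6) from Low to High. Position 59584018 near LOC118943836 on chromosome 23 was at 94.0% ± 2.44 in Low and at 100% in every Medium and High library read there. Position 4636299 on chromosome Y was at 34.1% ± 37.3 in Low, 6.25% ± 12.5 in Medium and 1.79% ± 3.57 in High (n = 4 each).

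No CpG separated the families past the threshold. Among 37747 CpGs the moderated quasi-binomial test called 0 between families and 1116 had an unadjusted p under 0.05. The smallest p was at position 5988359 on chromosome Y (adjusted p = 0.26 in the moderated quasi-binomial test), with a family B mean of 40.4% against 69.9% in family A. For the interaction of diet and family, 0 of 23547 CpGs passed, 578 had an unadjusted p under 0.05 and the plain test called 619. The smallest interaction p fell at position 15603700 on chromosome 26. In simulated data this interaction test recovered 0.8% of 40-point changes, so changes of that size would mostly be missed.

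Gene groups were fixed before the data were examined. In the choline, methionine and folate cycle list, 7, 6 and 9 members were tested for High against Medium, Medium against Low and High against Low, and 0 passed over all genes. Adjusted over the list alone, cth1 passed between High and Medium (-22.57 points, adjusted p = 0.022 in the moderated quasi-binomial test). At 15 shared positions its difference was -0.27, and the symbol can also stand for a zinc finger gene rather than cystathionine gamma-lyase. Other members had summed differences such as -12.37 points for sardh, sarcosine dehydrogenase (0.5 at 13 shared positions), and 21.7 for the choline kinase gene chkb (13.03 at 3 shared positions) between High and Low, with an adjusted p over the list alone of 0.19 and 0.31 in the same test.

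For the growth hormone, insulin and IGF list, 8 of 11 members had higher summed levels in High than in Low. The median difference was 5.45 points, at the 96.8th percentile of 10000 random lists, 1 of 30 list percentiles computed. At shared positions 8 of 11 were higher, with a median of 2.28 points, but these were not the same members: irs2a, irs1, ghr and insrb, 4 of 11, took the other direction there. The gene of stat5, a transcription factor that acts downstream of the growth hormone receptor, was at 78.9% ± 6.63 (n = 6) in High and 68.2% ± 6.45 (n = 5) in Low. Of its 34 shared positions 27 were higher in High, by 8.9 points on average. Neither stat5 nor irs2a, an insulin receptor substrate gene at -14.1 points by sums and 2.28 at 7 shared positions, passed over the list alone (adjusted p = 0.18 each, moderated quasi-binomial test).

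In the other lists 0 members passed over all genes. Among liver and yolk markers, tfa, for transferrin, passed between High and Low adjusted over the list alone (11.2 points by sums, adjusted p = 0.035, moderated quasi-binomial test), with -1.09 points at 8 shared positions. Among neural adhesion and synapse genes, the neuroligin gene nlgn3a was 20.3 points higher in High than in Medium by sums and 0.94 points higher at 18 shared positions (adjusted p over the list alone 0.14 in the same test). The muscle list, with ryr1b, pax7a and mef2cb among 8 members tested between High and Low, had a median summed difference of 0.53 points. The lipid list (pparg, acaca, elovl6 and ppardb) had 0.12, the homeobox list (shha, shhb, sox9 and pax9) 0.78 and the DNA and histone methylation enzymes (setd2 and kmt2d) 2.34. The immune list and the blood list had 1 tested member each, stat1b and slc4a1b, with 0.36 and -0.05 points between High and Low by sums. The general comparison list of cytoskeleton and channel genes had 0 tested members.

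The authors' deposited tables list differential CpGs within 10 kb of a transcript, 305 for High against Medium (165 hypomethylated, 140 hypermethylated) and 377 for Medium against Low (236 and 141). The reference diet of these tables is not given in the sources used here, and directions are printed as deposited. At the CpGs placed on the library files, hypomethylated in the table for Medium against Low went with a higher level in Medium, as described below. Per the authors' deposited table for High against Medium, genes with 3 CpGs or more included ppp2r2ab, a regulatory subunit of protein phosphatase 2A (4 hypomethylated), epob, an erythropoietin gene (3 hypomethylated), and the lipid flippase gene atp8b4 (3 hypermethylated). Per the authors' deposited table for Medium against Low, the sialyltransferase gene st6gal2b had 10 hypomethylated CpGs, VSX1, a homeobox gene of the visual system, had 4, and the spectrin gene sptbn5 had 4 and 1 hypermethylated CpG. In that deposited table hivep3a and tgm2l had 3 hypomethylated CpGs each, and ltbp1 and C1QTNF1 had 3 hypermethylated CpGs each.

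Members of the fixed lists in the authors' deposited tables were few, and their directions are again as deposited, with hypomethylated in Medium against Low going with higher levels in Medium at the placed CpGs, gbrap among them. In the choline and folate list the phosphatidylcholine transfer gene pctp was hypomethylated in the authors' deposited table for Medium against Low. In the growth hormone list the somatostatin receptor gene SSTR1B was hypomethylated in both deposited tables, and ghr, the growth hormone receptor, hypermethylated for Medium against Low. In the neural list all 7 CpGs of the authors' deposited table for Medium against Low were hypomethylated, at gbrap, grm8a, ndnf, nptxra, pcdh10a and pcdh2aa15. In the homeobox list 7 of 8 were hypomethylated, at VSX1, brinp1, meox2b and tbx15, and onecut3b was hypermethylated. Of these, brinp1 entered by a phrase in its description and is a neural gene.

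Of the features in the authors' deposited tables, CpG islands had the most uneven split, with 31 CpGs deposited as hypomethylated and 9 as hypermethylated for Medium against Low, whichever diet is the reference. By Fisher's exact test against all other CpGs of that table this gave p = 0.04, adjusted 0.22 over 8 tests. Exons of that table were split almost alike, with 30 hypomethylated and 9 hypermethylated CpGs (Fisher's exact p = 0.056, adjusted 0.22). Promoters held 44 hypomethylated and 23 hypermethylated CpGs (exact p = 0.68, adjusted 0.68). These tests take CpGs as independent, but the 377 CpGs of that table fall in 289 transcripts. Neighbours can share a direction, as the 10 CpGs of st6gal2b do, so the p-values may be too small.

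Both deposited tables shared 53 CpGs, and all 53 carried the same direction in both, 31 hypomethylated and 22 hypermethylated. The tables share the Medium libraries, so their directions are not independent. Genes in both included klhl21, leap-2b, ltbp1, tgm2l, epob and grm8a, named here by their number of CpGs after the tables were seen. The deposited tables give distances to transcripts but no chromosome positions, and 9 transcripts could be placed on the positions of the library files. At the placed CpGs with a difference, 17 of 17 (High against Medium) and 23 of 23 (Medium against Low) had the deposited direction as the other diet minus Medium. Many of these CpGs are neighbours, such as those from 23336994 to 23337132 on chromosome 18, each read in 1 Medium library. The counts are therefore not of independent CpGs. At st6gal2b on chromosome 18, position 23337132 was at 100% in the single Medium library read there, 37.0% ± 13.3 (n = 4) in Low and 31% ± 9.27 (n = 4) in High. Of the 41 placed CpG entries 0 were tested here. At least 4 libraries of both diets were read at 1 entry for High against Medium and at 2 for Medium against Low, but some of these libraries came from families read in 1 diet alone, which the tests leave out.

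**Figure D4:**
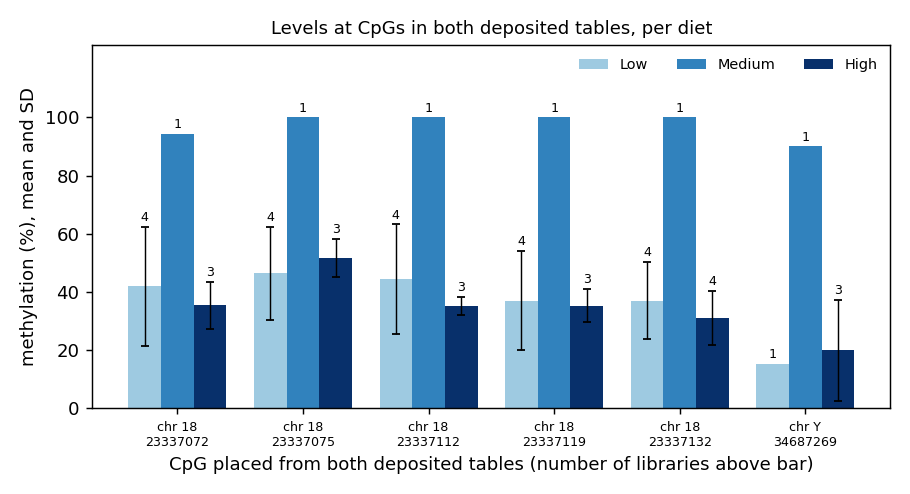
Methylation (%) at 6 CpGs of st6gal2b and leap-2b, of the 7 placed from both deposited tables, as diet means with SD bars, labelled by chromosome and position, with the number of libraries above each bar. Medium is highest at all 6 CpGs drawn, and several bars rest on 1 library and carry no SD.

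Per the authors' deposited tables that join methylation and expression, klhl21 and leap-2b, a liver-expressed antimicrobial peptide gene, were hypomethylated for High against Medium, with log2 expression changes of 2.54 (SE 1.37) and -3.35 (SE 1.73). For Medium against Low the deposited table gave gadd45ga, a stress-response gene, as hypomethylated with a log2 change of 1.67. The adjusted p in the authors' deposited tables was 0.906 for klhl21 and leap-2b and 1 for gadd45ga. Over all 5 gene and comparison pairs of these tables Fisher's exact test of methylation against expression direction gave p = 1.0, and the smallest p it could give was 0.2.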

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

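The counts of other splits and the tests of a mislabelled family and of spread beyond read sampling were set before their results were seen. The tests of the Low family A pair, of a level rising over all 3 diets and of shallow coverage were chosen after the results.

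Libraries stood far from their group in 7 of 48 groups tested, where chance gives about 1 in 20, or 2.4. Of these groups 30 were levels at CpGs named for their small p, where ties at 0% or 100% are common, so the numbers are not strictly comparable. Low family A sire 2 had a mean level of 55.77% over all its positions, against 67.4% to 70.3% in the other Low libraries. In that library 15.54% of positions had 20 reads or more, against 8.56% to 9.59%. At its 162887 positions read in at least 4 other libraries it averaged 51.7% and the others 53.4%, a difference of -1.69 points. The remaining 44.6% of its positions were not compared. In Medium family B sire 2, the smallest library, 29.93% of positions had 20 reads or more, against 8.72% to 12.5% in the other Medium libraries.

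Single libraries also stood apart at 4 of the named CpGs. At position 19504362 on chromosome 27 near LOC110507703, High family A sire 2 was at 63.64% and the other 3 High libraries at 0%. At position 23635671 on chromosome 13 in LOC110485993, High family B sire 1 was at 91.67% and the others at 100%, with only 10 to 15 reads per library. At position 47291278 on chromosome 1, Low family A sire 2 was at 50% and the others at 66.7% to 71.2%. At position 82493 of an unplaced scaffold, High family E sire 2 was at 96.0% and the others at 84.8% to 87.5%.

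Mitochondrial CpGs, which no comparison used, had a median level of 2.72% over the 17 libraries (1.68% to 6.6%). Their 485353 reads would allow a level of 0.0006% if none were called methylated, for counting error only. Incomplete conversion was not tested.

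Plain logistic calls were mostly higher outside the Low diet, with 159 of 199 higher in Medium and 130 of 170 higher in High. Spread between libraries beyond read sampling remains open as the explanation, since 16 of 100 splits of the libraries gave as many Medium against Low calls. The highest other split gave 782. The other splits had a median of 59 calls, against 0 in simulated unchanged data with read sampling alone. The libraries thus spread beyond read sampling, but whether this gave the direction of the calls was not tested. The Low family A pair cannot be told apart from its family: without both, 11 calls were left, against 50 to 838 without any other pair of Low libraries, but this takes all of family A out of the test, as leaving out both Medium family A libraries does (11). A level that rises with choline over all 3 diets also stays open: 11 of the 45 High against Medium calls were higher in High, but 43 of 100 splits gave as many calls, and of the plain trend calls 245 rose and 34 fell. An effect of the Low diet in family A may be real or come from those 2 libraries or the other family A libraries, and the family of Low family A sire 1 is in doubt by its file code.

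Chance cannot be excluded for any count of calls for which splits were run, and none were run for limma. For the plain test High against Medium, 43 of 100 splits gave 45 or more, with 308 as the highest other, and for High against Low 25 of 100 gave 170 or more, with 902 as the highest. For the plain trend 7 of 100 gave 279 or more, with 505 as the highest other, and for the plain interaction 33 of 100 gave 619 or more, with 1140 as the highest. Splits with several times the real count point to a structure of the samples or to more spread between libraries than was simulated, and neither was tested: a read correlation of 0.02 alone gave 157 to 170 plain calls in unchanged data. For the moderated test the real counts were 0, so 100 of 100 splits were as large. The highest other counts were 0 for CpGs in each diet comparison, the trend and the families. For tiles they were 6 (High against Medium), 45 (Medium against Low) and 39 (High against Low), and for genes 2, 1 and 1. With the prior from CpGs at 5 to 95%, 8 of 100 splits reached the 18 family calls (highest other 278) and 18 of 100 the 108 interaction calls (highest other 605). Splits for the diet comparisons exchanged libraries within families, but those for the interaction exchanged all libraries freely over diets and families. The latter also turn differences of diet or family into interaction calls, so they cannot show how many interaction calls chance alone gives.

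Low family A sire 1 stood apart from its family on 200 CpGs chosen, without it, to part families A and B. On a scale from 0 (family A) to 1 (family B) it scored 0.535, against 0.279 to 0.446 in the other family A libraries and 0.355 to 0.568 in family B. A mislabelled family would predict this. However, the family ranges overlap and family E spans 0.29 to 0.575, so the score cannot tell it apart from ordinary spread. That the overlap matters was considered only after the score was seen. Over the common CpGs the library's deviations from the Low mean correlated at 0.194 with High family B sire 2, the highest of all pairs compared. With Medium and High family B sire 1 they correlated at 0.148 and -0.05, and with family A libraries of the other diets at -0.095 to -0.064. This measure did not follow family in general, with means of 0.007 over pairs of the same family and -0.003 over pairs of different families. High family B sire 2 and Low family B sire 1, of the same family, correlated at -0.189, the lowest of all pairs compared. The pairs are also not independent. These values therefore cannot decide between the title and the file code, and a mislabelled family stays open. Shallow coverage is argued against by the 191107 positions of Low family A sire 1, more than Medium family A sire 1 has, and no biological explanation was tested.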

How the results depend on the processing

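The dispersion priors, the fits without both Low family A libraries, the 1-library fits, the shared-position means and the left-out libraries for genes were chosen after seeing the data, all others before. For the counts of calls and mean levels, 85 settings fixed in advance gave the same outcome, 15 moved and 1 reversed, and of 155 fits without a library 150 gave the same. Named CpGs and genes, chosen for small p in these same libraries, kept their direction in the 283 settings fixed in advance, which is no independent support. In 20 of these settings they passed the threshold, all by the plain logistic test except trip11 with gene bodies alone. They also kept their direction in 370 fits without a library. In 75 of these fits the value was identical, at 6 of the 37 results in every fit. There a library that a result needs could not be left out. Values moved by over 1.5 times at 3 results: position 82493 (8.84 points, 5.65 to 14.68), position 82508 (8.34, 4.71 to 11.98) and LOC110507399 (32.42, 18.54 to 35.54).

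The plain logistic test, which ignores spread between libraries, called 45 CpGs (High against Medium), 199 (Medium against Low), 170 (High against Low), 279 (trend) and 619 (interaction). At 0.01 and 25 points it called 17, 21, 24 and 34 for the first 4, and with 1 library per diet 128, 157 and 134. Without both Low family A libraries, which takes family A out of the test, and with at least 3 libraries per diet, it called 11 (Medium against Low) and 22 (High against Low). By limma 2, 2 and 1 CpGs were called. Its 2 High against Medium calls shared 0 CpGs with the 2 found with the prior from CpGs at 5 to 95%. The other priors left the diet comparisons and the trend at 0. For the interaction, priors from 2 to 98%, 5 to 95% and 10 to 90% gave 136, 108 and 1 calls, and 20 reads gave 1. Between families, priors from 2 to 98%, 5 to 95%, 10 to 90% and 20 to 80% gave 14, 18, 4 and 1, and 20 reads gave 2. In unchanged simulated data with a correlation of 0.02, the prior from 5 to 95% gave 27 false interaction calls and 2 false family calls. The causes were not tested further.

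Gene bodies alone gave 1 gene between High and Low, trip11 (-27.6 points, adjusted p = 0.017 in the moderated quasi-binomial test, against 0.13 with flanks). At shared positions trip11 differed by -0.68. For the 5 genes of smallest p per comparison, cth1 and tfa, the direction reversed at shared positions for LOC110510766 (-0.38), LOC110507399 (-0.43), peak1 (-2.07), LOC110525177 (-1.49) and tfa (-1.09), and the 12 other values moved by over 1.5 times. Other genes reversed too, such as irs2a (2.28). A sum takes different positions in each library, which is how these values can part.

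Leaving out each library gave 0 to 1 tiles for Medium against Low and 0 to 2 for High against Low. The single tile and both tiles came without Low family B sire 1, and 1 tile without High family B sire 2. The mean level difference ranged from -0.056 to 0.383 (High minus Medium), 0.487 to 1.407 (Medium minus Low) and 0.54 to 1.429 (High minus Low). Without High family B sire 2, High minus Low passed, at 0.979 (exact p = 0.0278). Without Low family B sire 1, which takes family B out of the test, the fits could not pass. Their 36 arrangements allow no exact p below 0.0556, the value obtained. The difference reversed without both Low family A libraries, to -0.276 (Medium minus Low) and -0.004 (High minus Low). With reads pooled over CpGs the differences were 0.31 (High minus Medium), 0.104 (Medium minus Low) and 0.414 (High minus Low), and over all CpGs of each library 0.791, 1.807 and 2.599, with exact p of 0.1852 or more.

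With no replicate block the mean level difference of High minus Medium reversed to -0.021 (exact p = 0.9632), and Medium minus Low was 0.92 (exact p = 0.0952) and High minus Low 0.9 (exact p = 0.0844). That fit left the counts of calls for CpGs, tiles and genes at 0, and a block of family and sire, not run for genes, those for CpGs and tiles. At least 5 reads could not be run, since no position has fewer than 10. Deposited CpGs at 20 reads gave no High against Medium value, and the strictest deposited entries could not be chosen, as no sizes are given. Depth limits single CpGs, whose median coverage was 11 to 14 reads.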

Other observations

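The tests of deposited directions and the plain-test overlaps in this part were chosen after the deposited tables or calls were seen.

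Intermediate CpGs, at 20% to 80% over all libraries, were where the diets lay farthest apart in points, and also where libraries of a diet spread most. Over 3074 such CpGs the level was 61.7% ± 2.43 (SD, n = 5) in Low, 64.6% ± 2.13 (n = 5) in Medium and 64.3% ± 2.27 (n = 6) in High. High minus Low was 2.17 points (exact permutation p = 0.194). CpGs at 80% or more, 73.4% of the common CpGs, stood at 90.8% ± 0.58, 91.3% ± 0.5 and 91.3% ± 0.44. There High minus Low was 0.5 points (exact permutation p = 0.167). The smallest p of any class was below 20%, where High minus Medium was -0.28 points (exact permutation p = 0.065). The intermediate class thus did not stand out from the others by its p.

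Gene groups lay at different median levels over all libraries, but none stood apart from random lists. The median summed level was 84.6% over 5 lipid genes, 74.1% over 11 growth hormone and IGF genes, 32.4% over 8 muscle genes and 17.5% over 5 homeobox genes, against 58.2% over 9811 genes. The smallest permutation p against random lists was 0.1, for the lipid genes (adjusted p = 0.42 by permutation over 7 lists).

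All 53 CpGs in both deposited tables carry 1 direction, which has 3 explanations that the placed CpGs bear on. If Medium is the reference of both tables, placed Medium against Low CpGs should take the deposited direction as Low minus Medium. Of those with a difference 100% did, such as at st6gal2b and gbrap, but many are neighbours in the same transcript and not independent. A level that moves steadily with choline would put Low and High on opposite sides of Medium. If Medium is the reference of both tables, the shared directions put them on the same side, as deposited. The Medium mean lay between the other means at 0 of 7 placed CpGs in both tables, but this follows from the same directions. At 6 of 7 the Medium mean rests on 1 library, so the true levels at these CpGs stay open. That the calls rest on few libraries also stays open, as the median placed CpG had 1.0 library in its least covered diet. The Medium libraries are in both tables, which alone could give a shared direction, and no biological explanation was tested.

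Both comparisons that share the Medium libraries had opposed differences, as shared libraries alone give. Across 34226 CpGs, which are not independent, the correlation of High minus Medium with Medium minus Low was -0.502, against -0.505 in simulated unchanged groups. The covariances were -12.7 and -11.22, a difference of -1.48. The simulation shuffled deviations from the diet means, which spread less than the libraries themselves, so its covariance is too small in size. The difference of -1.48 therefore cannot be read as more than the shared libraries give. By the moderated test 0 CpGs were called in both. By the plain test 6 CpGs were higher in Medium than in both other diets, and how many the shared libraries alone would give was not tested.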
